A study of Capra hircus with 198 samples.

How the data were processed

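The series holds total RNA sequencing of 33 tissues from the same 6 adult female Murciano-Granadina goats, 198 libraries in all. Per the labels, goats 2, 3 and 6 were lactating and goats 54, 64 and 73 were dry. The labels' protocols name the RiboPure kit for extraction, a strand-specific VAHTS Universal kit for the libraries and an Illumina NovaSeq instrument. The submitters' processing notes name STAR, StringTie and edgeR, with no versions and no roles. The labels name no genome build and no library batch.

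The authors deposited a table of expected counts per gene and library, which holds 39734 features. Of the values above 0 in this table, 37.0% had a fractional part, and the values were rounded for the fits. The deposited table named for gene length holds natural log offsets that join library size and gene length, since counts divided by the exponent of these values gave the CPM-named table up to 1 constant. These offsets served only as an alternative scaling. The deposited CPM-named table holds a signal whose columns do not sum to the same total, in which all 6 values of some gene and tissue pairs are set to 0. It ends part way through the gene list and was held in part, so no result rests on it. The authors deposited a tau score, a fraction from 0 for even expression to 1 for expression in a single tissue, with no formula. The deposited lncRNA annotation gives 1-based positions and names StringTie in its source column, and it was used only to sort features into lncRNA and other genes. Of the features not in that annotation, 23502 matched the RefSeq table of assembly ARS1.2, which was used only for names, classes and neighbours.

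CPM values were computed here from the count table with each library's total. Total counts ran from 1.31 to 8.97 M counts, with a median of 4.63 M. A floor of 3 counts stood at 2.29 CPM in the library with the lowest total and at 0.335 CPM in the library with the highest. Where every library of a group was at 0, a fold is given as a lower bound against 3 counts over that group. Intervals and floors cover counting error only. Values are means with the SD over goats.

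The labels do not say how the counting used the strand of a read, so counts of a gene and of a feature on its other strand, or of overlapping genes, cannot be told apart with certainty. The same holds for reads shared between near-identical copies of a gene. Of 287 genes picked for naming, 54 (18.8%) overlap another gene in the RefSeq annotation. Those printed include ACACA, ATP2C2, ATP6, CA9, COX3, FAM46A, SLC16A10 and TFRC.

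Within each tissue, lactating and dry goats were compared with edgeR (version 4.0.16, R 4.3.3). Genes passed filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood F-test of glmQLFit was adjusted by Benjamini-Hochberg at 0.05. The standard error of a log2 fold change is its size divided by the square root of F. The same fit compared 5 pairs of tissues over 6 against 6 libraries. The pairs share their goats, and a check of whether residual profiles matched the same goat across both tissues found the own goat best for between 3 and 5 of 6 goats. The main fit, fixed before the data were examined, leaves this pairing out, and a fit with the goat as a block was its alternative. The effect shared by the 32 tissues other than the mammary gland was tested with limma (version 3.58.1, eBayes with trend) on each goat's mean log2 CPM with a prior count of 2, for genes with a mean of at least 1 CPM in at least 1 tissue. The same test on each goat's mammary value minus its mean over the other 32 tissues asked whether the mammary effect differed. All of these tests are two-sided.

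Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists tested in a tissue, with at least 3 measured members. Camera asks whether a list's genes stand apart from the other genes. With an estimated correlation, camera called none of the lists in any of these comparisons at this adjusted threshold. Fry, run beside it, asks whether a list's genes move on balance in 1 direction, and it compares them with no other genes. Of the planned lists it called 7 in the mammary gland, 3 in the adenohypophysis and 3 body-wide, and of 5 body-wide lists chosen after the data were seen it called 3.

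Tau was computed over the 33 tissue means of log2(CPM + 1). A gene was called tissue-enriched when its mean in a tissue was at least 1 CPM and at least 5 times that of the next tissue, and each of the 6 libraries lay above all 192 others. Library identity was the tissue whose mean profile, without the library itself, had the highest Spearman correlation. The tau of lncRNAs was set against that of other genes by a permutation test with 1e+05 resamples, also within 10 bins of the highest tissue mean.

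Groups, tests, lists and most alternatives were fixed before the data were examined, and so was the rule for naming genes. The rule named up to 4 called members of each list, or the 2 members with the smallest p where none was called, in the 6 tissues described in full. It named the 8 largest rises and 8 largest falls in the mammary gland among genes with a symbol, a mean of at least 1 CPM and no overlap between the groups, and the 3 largest each way in other tissues. It named the 10 features called in most tissues in the same direction, and up to 4 genes per list and the 4 largest each way in each tissue pair. It named the marker with the highest mean per tissue, the top tissue-enriched gene, any feature with at least 5% of counts, the 5 lncRNAs with the highest tissue mean, and the 3 largest lncRNA rises and falls in the mammary gland. Values are printed for most of these genes, some results are not reported here, and genes chosen after their values were seen are marked as such.

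Alternatives were RLE, total counts and the offsets as scaling, no count filter, DESeq2 (version 1.42.0), a single fit over 198 libraries, a minimum log2 fold change of 1, each goat left out in turn, and settings without lncRNA features or without libraries closest to another tissue. The tests were run on simulated counts with 200 changed genes. At a 4-fold change the mammary comparison recovered 7% of these genes, liver 44%, subcutaneous fat 21%, adenohypophysis 58%, hypothalamus 42% and duodenum 42%. The tissue pairs recovered between 53% and 85% at a 4-fold change, and the body-wide test recovered 96%. At a 2-fold change the single-tissue comparisons recovered from 0% to 14% and the body-wide test 65%. Changes of 2-fold within a tissue were therefore mostly out of reach. Most 4-fold changes were missed too in each of these single tissues but the adenohypophysis.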

Results

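The data cover 33 tissues of 6 adult female dairy goats, 3 of them lactating and 3 dry, with 1 library per goat and tissue. The series asks how genes and long noncoding RNAs (lncRNAs) are spread over the tissues of the goat, and the labels add lactation state as a factor. Each tissue therefore has 6 libraries, and each state within a tissue has 3. Total counts per library had a median of 4.63 M, with the lowest tissue median in the hippocampus (1.64 M) and the highest in the heart (8.07 M). The same 6 goats stand behind every tissue, so tissues are not independent replicates of a difference in state. Lactation state is also inseparable from any other way in which the 2 sets of goats differed, such as age, housing or day of sampling, on which the labels give nothing. Values below are mean CPM ± SD, with n = 3 goats per state and n = 6 per tissue unless said otherwise. A gene named as higher or lower was separated in every goat of a state unless a clause says otherwise, and chance alone separates 3 against 3 goats for 10% of genes.

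Noncoding features held most of the counts. The 14511 annotated lncRNA features took 85.0% of counts on average (77% to 90.9% per library), and 20566 protein-coding genes took 13.6% (8.28% to 21.2%). KLHDC1-AS1, an antisense feature of a kelch-domain gene, took at least 5% of counts in all 33 tissues and peaked at 16.6% in the abomasum (165713 CPM). LINC07885 reached 18.9% in the heart (189086 CPM) and PGK2-AS1, antisense to a glycolytic kinase gene, 10.7% in the ovary (106658 CPM). LINC22482 followed with 63628 CPM in the masseter muscle and LOC106503064-AS1 with 59737 CPM in the mandibular lymph node, and LINC22484 (5.72%) and LINC00809 (5.59%) peaked in the heart and LINC59933 (5.09%) in the adrenal medulla. Antisense features as a class held 35.3% of counts and intergenic ones 24.6%. The antisense feature of ND4, a mitochondrially encoded subunit of complex I, averaged 10483 CPM against 85.5 CPM for ND4 itself, and it was the higher in all libraries (100%). For ND5 the antisense feature averaged 1614 against 510 CPM and was the higher in 132 libraries. How the counting used the strand is not given in the sources used here, so values of genes with an antisense partner are uncertain. With antisense features left out, lncRNAs took 76.5% of the remaining counts.

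**Figure D1:**
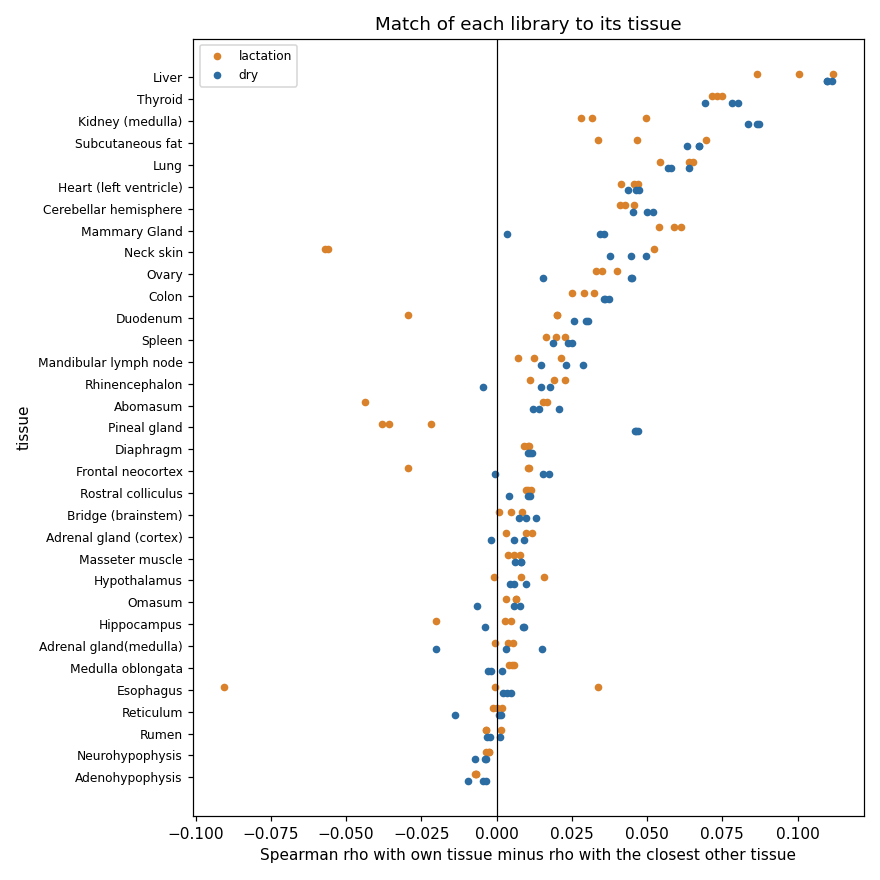
Spearman correlation of each library with the mean of its own tissue minus that with the closest other tissue, by tissue. Lactating and dry goats are in separate colours, and a library left of the vertical line lay closer to another tissue. In all, 159 libraries lay closest to their own tissue. The lowest correlation with the own tissue, not drawn itself, was 0.743, in the abomasum of goat 2.

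Of 132 marker genes set for the 33 tissues, 77 had their highest mean in their own tissue and 106 had it among the 3 highest. The genes named here are those with the highest mean in each tissue. Albumin (ALB) reached 17882 ± 7355 CPM in liver, thyroglobulin (TG, the thyroid hormone precursor) 14103 ± 5063 in thyroid, and the surfactant gene SFTPC 1384 ± 355 in lung. The kappa-casein gene CSN3 averaged 4939 CPM over the 6 mammary libraries, growth hormone (GH1) 881 ± 761 in the adenohypophysis and the adipokine ADIPOQ 793 ± 502 in subcutaneous fat. Muscle creatine kinase (CKM) stood at 2059 ± 662 in masseter and 1415 ± 532 in diaphragm, and cardiac troponin I (TNNI3) at 183 ± 31.9 in the left ventricle. Keratin genes marked the lined upper tract, with KRT4 at 3422 ± 2982 in esophagus and KRT6A at 534 in rumen, 628 in reticulum and 816 in omasum, while KRT10 reached 509 ± 486 in neck skin. Further down, the mucin MUC5AC stood at 246 ± 251 in abomasum and the fatty acid binding protein FABP2 at 67.0 ± 60 in duodenum. The steroid carrier STAR reached 496 ± 88.0 in adrenal cortex, the granule protein CHGA 429 ± 407 in adrenal medulla and the salt transporter SLC12A1 243 ± 259 in kidney medulla. Myelin basic protein (MBP) was at 444 ± 104 in the bridge of the brainstem and 406 ± 164 in medulla oblongata, and CBLN1, a cerebellar synapse organiser, at 33.2 ± 4.40 in cerebellum. The complement receptor CR2 stood at 52.4 in lymph node and 33.6 in spleen, the glutamate transporters SLC17A7 at 11.6 in hippocampus and 10.3 in frontal neocortex and SLC17A6 at 11 in rostral colliculus, and reelin (RELN) at 14.6 in rhinencephalon. FOXL2, an ovarian factor, averaged 4.28 in ovary, the neuropeptide precursor PMCH 7.93 in hypothalamus, the developmental factor RAX 0.305 in neurohypophysis, and TPH1, which starts melatonin synthesis, 47.0 ± 55.7 in the pineal gland. The RAX mean lies below the 3-count floor even of the library with the highest total (0.335 CPM), too low to mark its tissue.

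By correlation of whole profiles, 159 libraries lay closest to their own tissue and 39 did not. All 12 libraries of the adenohypophysis and neurohypophysis were closest to the other lobe, whose mean holds a library of the same goat. With that goat left out of every tissue mean, a choice made after the data were seen, 175 libraries lay closest to their own tissue and 23 did not, among them 7 of the pituitary. The other 27 that differed included 4 rumen, 3 pineal and 2 esophagus libraries. The 3 pineal libraries were those of the 3 lactating goats, which lay closest to frontal neocortex, rhinencephalon and hypothalamus. In goat 2 the abomasum library lay closest to duodenum (0.786 against 0.743 for abomasum) and the duodenum library closest to abomasum (0.928 against 0.899).

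Liver had by far the most private genes. Of 482 tissue-enriched features, 307 genes and 175 lncRNAs, liver held 231, and ALB stood 3637-fold above its next tissue. Mammary gland held 66, all of them lncRNAs, led by LINC65185 at 1908 CPM, and thyroid held 52, led by TG. The libraries of a tissue pool both states, so milk genes at 0 CPM in a dry gland, such as CSN2 and LALBA, could not pass. By means alone mammary gland held 153 features. RYR2, the calcium release channel of heart muscle, led the 19 of the heart at 606 CPM against 67.8 in the next tissue, and SFTPC led the 19 of the lung. ZIC1-AS1 (1142 CPM) led the 22 of the cerebellum and PAQR5-AS1 (1272 CPM) the 17 of the kidney medulla, and 15 tissues had none. Since every library of a tissue has to pass, a library closest to another tissue can bring its count to 0. Without such libraries the total was 874, with 235 in liver, 148 in the pineal gland, 117 in neck skin and 45 in abomasum, all but liver at 0 before. Tau was at least 0.8 for 4456 of 31305 expressed features (14.2%), with a median of 0.441. The tau the authors deposited was at least 0.8 for 9133 of 33323 features. Over the 31155 shared features it was so for 6975, against 4315 by the value here, and it differed from the value here by a median of 0.0375 (Spearman rho 0.974, across genes, which are not independent replicates).

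Features annotated as lncRNAs were less tissue-bound than other genes at high abundance. Their median tau was 0.343 against 0.482 for other genes, a difference of −0.138 (permutation p = 1e-05, the smallest these permutations can give). This test, also within bins, permutes features, which are not independent replicates. The difference changed sign with abundance. In the 4 bins with the lowest peak expression lncRNAs had the higher median, and in the 6 bins with the highest peak expression the lower, with 0.205 against 0.523 in the top bin. Averaged over bins the difference was −0.0712, and 8 of 10 bins had an adjusted p under 0.05. The class of a feature is that of the annotation, and the strand of the counts is uncertain. Without antisense features, a choice made after the data were seen, the difference was −0.116, and −0.329 in the top bin.

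The question for the mammary gland was which genes differ between milk-producing and dry glands. Milk protein genes dominated the answer. The beta-casein gene CSN2 averaged 7862 ± 928 CPM in lactating and 0.0683 ± 0.118 in dry glands (log2 fold change 16.41, SE 0.57, adjusted p = 1.31e-05), and the alpha-s2-casein gene CSN1S2 averaged 6045 ± 2544 against 0 in all 3 dry glands, at least 29063-fold higher (adjusted p = 0.00102). CSN3 averaged 9876 ± 5110 against 2.09 ± 3.44 (12.25, SE 1.35, adjusted p = 0.00585), and LALBA, the subunit that directs lactose synthesis, 830 ± 661 against 0.0651 ± 0.113 (13.23, SE 1.24, adjusted p = 0.00297). GLYCAM1, a milk glycoprotein, was at least 4983-fold higher, at 1036 ± 428 against 0 (adjusted p = 0.00108). The alpha-s1-casein gene CSN1S1 varied most among lactating goats, from 417 CPM in goat 3 to 21455 in goat 2, against a dry mean of 0.521 (14.11, SE 1.97, adjusted p = 0.0186), and this call was lost without goat 6, 64 or 73.

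Genes for milk fat followed. Butyrophilin (BTN1A1), which coats milk fat globules, stood at 153 ± 31.7 against 0.884 ± 1.21 CPM (7.59, SE 0.74, adjusted p = 0.00326). The lipid synthesis genes LPIN1 (36.7 against 0.644 CPM, 5.97, SE 0.79), SCD (23.4 against 0.592, 5.26, SE 0.80) and GPAM (39.7 against 1.16, 5.13, SE 0.79) were higher. Other transport and signalling genes were higher too. They were SLC1A1, a glutamate transporter (18.1 against 2.53, 2.96, SE 0.50), ATP2C2, a calcium pump of the secretory pathway that overlaps TLDC1 (33.3 against 3.46, 3.35, SE 0.54), SOCS2, a feedback inhibitor of STAT5 signalling (25.3 against 2.97, 3.2, SE 0.48), CIDEA, a lipid droplet protein (16.5 against 1.22, 3.81, SE 0.57), and FKBP5, a chaperone of the glucocorticoid receptor that glucocorticoids induce (34.9 ± 15.4 against 2.94 ± 2.47, 3.74, SE 0.67, adjusted p = 0.0426). The complement gene C9 (21.0 against 0, at least 101-fold), the calcium-mobilising hormone gene PTHLH (7.37 against 0, at least 35.4-fold), PTCHD3 (65.7 against 0.0683, 9.49, SE 0.74) and the giant muscle proteins TTN (90 against 12, 3.02, SE 0.34) and NEB (52.9 against 15.4, 1.89, SE 0.31) were also higher. Just 4 genes met the rule for falls. They were LYPD1, which overlaps GPR39 (6.83 against 28.6, −2.01, SE 0.36), SLC16A10, an aromatic amino acid transporter that overlaps LOC108636724 (10.5 against 37.9, −1.76, SE 0.32), TIPRL, a regulator of TOR signalling (13.3 against 43.6, −1.61, SE 0.30), and LRRC19, which overlaps IFT74 (79.0 in lactating glands, −1.25, SE 0.20). Among lncRNAs, RFX4-AS1 (60.8 against 0, at least 292-fold), LRRC8A-OT1 (53.7 against 0, at least 258-fold) and LINC17392 (25.2 against 0, at least 121-fold) were higher, and LOC108635849-OT1 (0.372 against 8.18, −4.27, SE 0.76), LOC108637953-OT1 (5.92 against 113, −4.19, SE 0.40) and SORCS1-AS1 (10 against 182, −4.03, SE 0.71) lower.

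**Figure D2:**
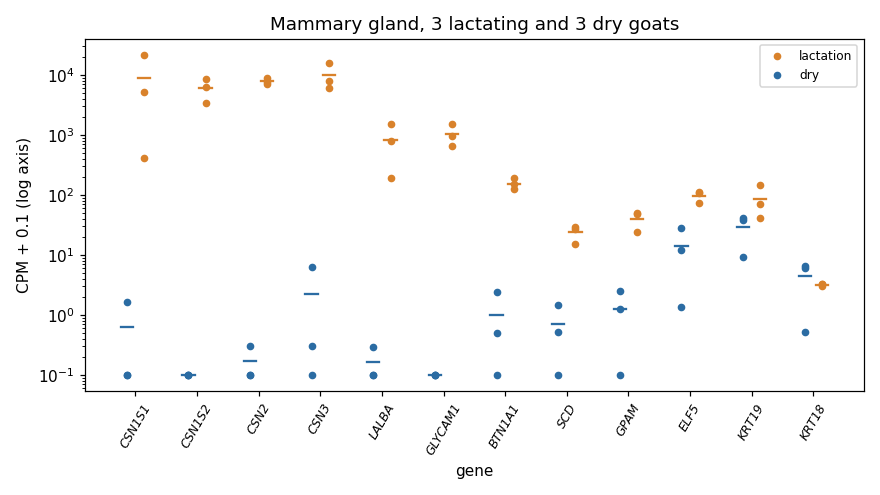
CPM plus 0.1 on a log axis for 12 genes in the 6 mammary libraries, with lactating and dry goats in separate colours and a bar at each group mean. CSN2 ran from 7096 to 8894 CPM in the lactating goats and from 0 to 0.205 in the dry goats.

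Of 18214 genes tested in the mammary gland, 159 were higher and 33 lower in lactation, 104 of them lncRNAs. The total was 37 without goat 73, 52 without goat 2, 52 without goat 6 and 88 without goat 64. CSN1S2, CSN2, CSN3, LALBA, GLYCAM1, BTN1A1, C9 and PTCHD3 passed under every alternative tried, while each of the other called coding genes named for this gland lost its call when at least 1 goat was left out (TTN without goat 73 alone). All members of the milk protein list (9 of 9) were higher, 7 of them called and 9 when adjusted over the list alone (adjusted p = 2.11e-24, and adjusted p = 0.213 with an estimated correlation). For milk fat synthesis and secretion, 8 of 23 members were called and 19 adjusted over the list alone (adjusted p = 7.47e-18, and adjusted p = 0.241 with an estimated correlation). Amino acid transport (1 of 8 called, 5 adjusted over the list alone, adjusted p = 3.91e-05), lactose synthesis and glucose uptake (1 of 8, 3 over the list alone, adjusted p = 0.00205) and cholesterol synthesis (1 of 11, 7 over the list alone, adjusted p = 7.13e-05) were also called, at adjusted p = 0.241, adjusted p = 0.241 and adjusted p = 0.263 with an estimated correlation. So were prolactin and STAT5 signalling (1 of 11, 2 over the list alone, adjusted p = 0.0038, and adjusted p = 0.603 with an estimated correlation), involution and acute phase (0 of 12, 3 over the list alone, adjusted p = 0.00126) and the glucocorticoid response (1 of 9, 1 over the list alone, adjusted p = 0.00244), the last pair at adjusted p = 0.535 with an estimated correlation. The other 15 lists, cell type lists among them, had adjusted p from 0.0865 to 0.792. Among these, fry called the adipocyte list (adjusted p = 0.0417) and the calcium transport and PTHLH list (adjusted p = 0.0426) as higher. Of the lists that camera called, fry did not call prolactin and STAT5 signalling (adjusted p = 0.253), involution and acute phase or the glucocorticoid response (both at adjusted p = 0.142). Of 10 splits of the goats into sets of 3, 4 called at least as many lists by camera as the real one, itself included. Epithelial ELF5 (96.4 against 13.7 CPM, adjusted p = 0.150) and KRT19 (85.0 against 29.5, adjusted p = 0.301), collagen COL1A2 (39.4 against 8.40, adjusted p = 0.273), the endothelial gene VWF (32.4 against 10.3, adjusted p = 0.143) and the plasma cell gene JCHAIN (75.4 against 58.7, adjusted p = 0.877) did not pass. The dry gland of goat 54 stood apart with low epithelial genes, at 4.91 CPM for KRT8 against 29.1 and 36.2 in goats 64 and 73, 2.05 for EPCAM against 28.9 and 19.2, and 1.23 for ELF5 against 27.7 and 12. With goat 54 left out of every tissue mean, this library lay closest to ovary (0.844 against 0.841 for mammary gland). FASN was low there too, at 1.84 against 54.3 and 20.1 (214 to 340 in lactating glands). Without goat 54 the milk fat list was still called (adjusted p = 1.96e-24, and adjusted p = 0.133 with an estimated correlation) and the prolactin list was not (adjusted p = 0.0554).

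In liver, the question was how the metabolism of lactating goats differs from that of dry goats. FKBP5 stood at 15.4 ± 8.75 against 0.706 ± 0.239 CPM (4.41, SE 0.69, adjusted p = 0.0111) and the chaperone HSPA8 at 165 ± 62.2 against 53.1 ± 3.61 (1.62, SE 0.28, adjusted p = 0.0193). Lower in lactation were SOCS2, an inhibitor of growth hormone signalling (7.05 ± 4.83 against 33.8 ± 3.75, −2.32, SE 0.45, adjusted p = 0.0295), PCK1, a key enzyme of gluconeogenesis (179 ± 97.1 against 521 ± 21.9, −1.55, SE 0.32, adjusted p = 0.0373), and GPAM, which starts triglyceride synthesis (11.1 against 36.6, −1.77, SE 0.35, adjusted p = 0.0311). The largest rises were PROB1 (14.5 against 0, at least 61.7-fold), GGT6 (4.56 against 0.0772, 5.41, SE 1.14) and TXNL4B (99.2 against 2.68, 5.20, SE 0.98), and the largest falls the RNA sensor TLR7 (0.519 ± 0.472 against 49.3 ± 20.7, −6.51, SE 0.61), AGBL2 (0.698 against 22.1, −4.99, SE 0.65) and GPRC5D (0.469 against 10.5, −4.45, SE 0.94). CPT1A, which admits fatty acids to mitochondria, did not pass (50.9 against 24.3, adjusted p = 0.0986). In all, 243 genes passed, 95 higher and 148 lower. The count was 45 without goat 54, 67 without goat 64, 109 without goat 73 and 132 without goat 6. Of 18 lists, the glucocorticoid response was called as higher (1 of 9 called, 2 adjusted over the list alone, adjusted p = 0.00802) and the mitochondrially encoded genes as lower (0 of 13 called, 1 over the list alone, 10 lower, adjusted p = 0.0363), both at adjusted p = 0.645 with an estimated correlation. Without goat 64, whose liver library stood apart, the mitochondrially encoded list was not called (adjusted p = 0.172). The other 16 had adjusted p from 0.0893 to 0.794.

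In subcutaneous fat, the store from which milk fat can draw, no gene passed, so the values that follow describe lists. The lipogenesis list was called as lower by camera (14 of 15 members lower, 3 adjusted over the list alone, adjusted p = 2.69e-08), but not with an estimated correlation (adjusted p = 0.876) nor by fry (adjusted p = 0.821). Of its members, ACACA stood at 163 ± 164 against 604 ± 173 CPM (adjusted p = 0.497) and ELOVL6 at 137 ± 127 against 748 ± 440 (overlapping between states, adjusted p = 0.471), while LIPE of the lipolysis list, the hormone-sensitive lipase, stood at 80.3 ± 53.0 against 15.7 ± 7.27 (adjusted p = 0.471). ZBTB16 (25.3 against 3.61, adjusted p = 0.471) and FKBP5 (59.8 against 10.3, adjusted p = 0.497), both glucocorticoid-induced, stood higher, and COX3, a subunit of cytochrome oxidase, lower (31.7 against 87.7, adjusted p = 0.424). Camera called 3 of 15 lists, lipogenesis and, beside it, the mitochondrially encoded genes (13 of 13 lower, 9 over the list alone, adjusted p = 3.15e-13, and adjusted p = 0.397 with an estimated correlation) and, as higher, the glucocorticoid response (2 over the list alone, adjusted p = 0.0396, and adjusted p = 0.876 with an estimated correlation). The other 12 had adjusted p from 0.0877 to 0.993. By edgeR 0 genes passed, with 1328 at an unadjusted p under 0.05 and 170 by DESeq2, and 4, 4 and 3 passed without goats 3, 6 and 54. With total counts alone as scaling the median of all genes moved from 0.04 to 0.39 on the log2 scale, and the medians of these lists kept their signs.

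In the adenohypophysis, the question was whether hormone genes differ with lactation. GH1 averaged 1438 ± 704 against 324 ± 147 CPM (2.33, SE 0.40, adjusted p = 0.00891), and CGA, the shared subunit of the glycoprotein hormones, 68.0 ± 23.8 against 23.2 ± 9.97 (1.75, SE 0.32, adjusted p = 0.0113). FKBP5 (13.3 against 3.70, 2.04, SE 0.43), the clock gene CLOCK (32 against 17.4, 1.08, SE 0.25), the chaperones HSPA8 (83.7 against 46.4, 1.04, SE 0.26) and HSP90AA1 (147 against 86.0, 0.97, SE 0.19) and the mitochondrially encoded COX3 (41.1 against 20, 1.23, SE 0.24) and COX1 (478 against 336, 0.71, SE 0.14) were higher. FAM46A, which overlaps LOC108636767, had the smallest adjusted p of the genes named here (59.0 ± 8.14 against 8.11 ± 1.60, 3.06, SE 0.24, adjusted p = 4.26e-05), and AMIGO2, an adhesion protein gene that overlaps PCED1B, was higher (12.1 against 1.37, 3.29, SE 0.53). The fat cell genes GPD1 (12.5 against 38.9, −1.46, SE 0.30) and LIPE (3.88 against 13.6, −1.61, SE 0.38) were lower, as were MYH15 (0.457 against 6.29, −3.50, SE 0.68), ISYNA1 (0.753 against 6.16, −2.77, SE 0.67) and KCTD21 (1.47 against 10.2, −2.59, SE 0.53). In all, 516 genes passed, 282 higher and 234 lower, which became 145 higher and 524 lower with total counts alone as scaling, where the median of all genes moved from −0.01 to −0.22. A single fit over all libraries called just 3 genes here. The count was 112, 311, 200, 246, 301 and 322 without goats 2, 3, 6, 54, 64 and 73. Called lists were the pituitary hormones and their regulators (14 of 15 higher, 2 called and 7 adjusted over the list alone, adjusted p = 7.48e-06, and adjusted p = 0.106 with an estimated correlation), heat shock (2 called, 5 over the list alone, adjusted p = 0.000789), the adipocyte list as lower (2 of 6, 2 over the list alone, adjusted p = 0.00422), both at adjusted p = 0.125 with an estimated correlation, and the mitochondrially encoded genes (3 of 12, 4 over the list alone, adjusted p = 0.0176, and adjusted p = 0.293 with an estimated correlation). The other 7 of 11 lists had adjusted p from 0.116 to 0.883. The dry library of goat 64 stood apart from its tissue (correlation 0.899, others 0.928 to 0.943), and 5 of the 6 libraries lay closest to the neurohypophysis even with their goat left out of every tissue mean. Without goat 64 the hormone list was still called (14 of 15 higher, adjusted p = 1.09e-05, and adjusted p = 0.132 with an estimated correlation).

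In the hypothalamus, the mitochondrially encoded list was called as lower (13 of 13 members lower, 5 adjusted over the list alone, camera adjusted p = 4.92e-13), but not with an estimated correlation (adjusted p = 0.204). CYTB of complex III stood at 612 ± 172 against 1175 ± 236 CPM (adjusted p = 0.692) and ATP6 of the ATP synthase at 123 ± 59.4 against 258 ± 6.50 (adjusted p = 0.692). The lactating library of goat 2 stood apart, with 8.28% of counts in protein-coding genes against 12% to 13.4% in the other 5. Without goat 2 all 13 members were still lower (adjusted p = 4.05e-15, and adjusted p = 0.295 with an estimated correlation). PMCH, the precursor of an appetite-linked neuropeptide, was at 0 in all 3 lactating goats against 15.9 ± 16.2 (adjusted p = 0.546). PMCH overlaps PARPBP. No single gene passed in edgeR (0, with 956 at an unadjusted p under 0.05 and 32 by DESeq2), and 4, 4 and 1 passed without goats 2, 3 and 64. The other 5 lists had adjusted p from 0.259 to 0.884.

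In the duodenum, the intestinal absorption list was called as lower in lactating goats (8 of 11 members lower, 0 adjusted over the list alone, adjusted p = 0.00834), but not with an estimated correlation (adjusted p = 0.659). Without goat 2, whose duodenum library lay closest to abomasum, 9 of 12 members were lower (adjusted p = 0.00497, and adjusted p = 0.611 with an estimated correlation). Sucrase-isomaltase (SI) was at 1.89 ± 1.78 against 17.8 ± 15.7 CPM (adjusted p = 0.296) and FABP2, which carries fatty acids in enterocytes, at 19.9 ± 17.2 against 114 ± 45.2 (adjusted p = 0.353). The immunoglobulin joining chain gene JCHAIN stood at 1146 ± 323 against 3081 ± 1851, with overlap (adjusted p = 0.296). The mitochondrially encoded genes were called as lower too (12 of 13 lower, 1 over the list alone, adjusted p = 0.0122, and adjusted p = 0.659 with an estimated correlation), and the other 11 lists had adjusted p from 0.287 to 0.644. By edgeR 0 genes passed, with 1837 at an unadjusted p under 0.05 and 166 by DESeq2. Without goat 2, 28 genes passed, and 1 passed without goat 3.

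**Figure D3:**
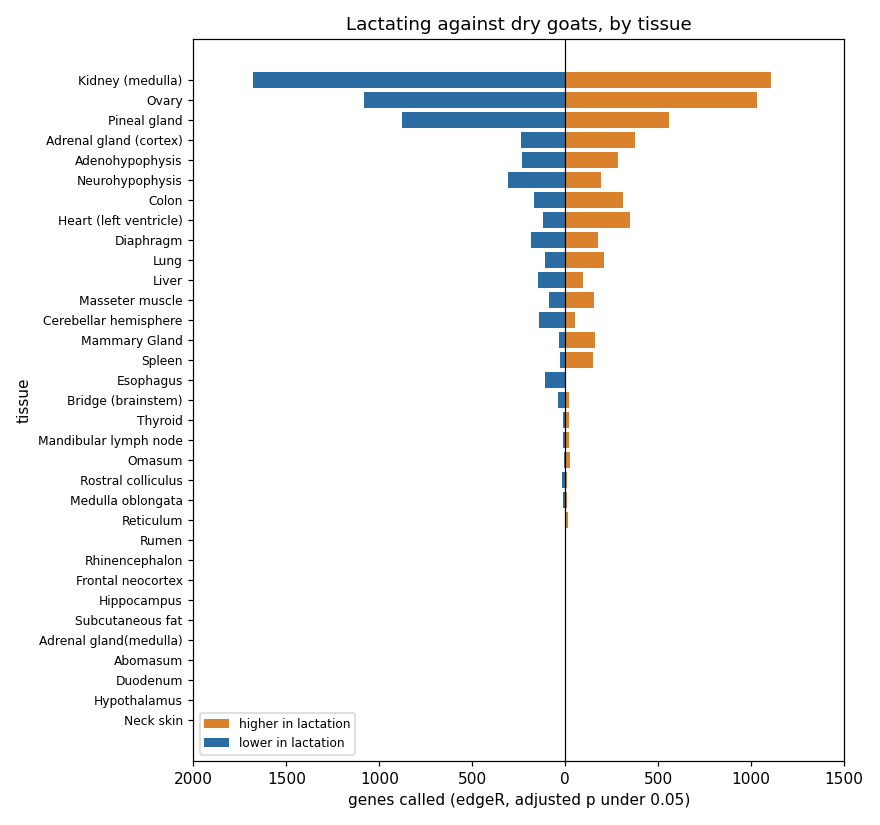
Number of genes called higher (right) and lower (left) in lactating than in dry goats in each of the 33 tissues by edgeR, at an adjusted p under 0.05. Kidney medulla had 2787 calls, ovary 2112 and pineal gland 1440, against 159 higher and 33 lower in the mammary gland.

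Summed over the 32 tissues other than the mammary gland, 10799 calls were made, 5189 higher and 5610 lower, and 22 tissues had at least 10. Without kidney medulla, ovary and pineal gland, set apart after their calls were seen, 4460 remained and the balance turned, with 2487 higher and 1973 lower. With total counts alone as scaling the sum was 15985, 10634 higher and 5351 lower. The sum was 6767 without goat 2, 6189 without goat 54 and 6047 without goat 64. Abomasum, adrenal medulla and neck skin had 0 calls by edgeR, as did the 3 tissues described above without calls. At an unadjusted p under 0.05 these 3 had 599, 876 and 1853 genes, and by DESeq2 21, 60 and 185. Neck skin had 1211 calls without goat 2. The lactating libraries that then remained were those of goats 3 and 6. With their goat left out of every tissue mean, they lay closest to diaphragm (0.896 against 0.848 for neck skin) and subcutaneous fat (0.907 against 0.863). These calls may therefore reflect what was sampled.

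Kidney medulla, ovary and pineal gland held the most calls. In kidney medulla, GATM, a creatine synthesis gene of the proximal tubule, was at 0 in lactating goats against 32.3 ± 14.9 CPM, at least 150-fold lower, and the anion transporter SLC22A8 (0 against 21.2, at least 98.5-fold) and the carnitine gene BBOX1 (0 against 14, at least 65.2-fold) were lower too. The urea transporter SLC14A1 (4.31 against 0, at least 23.1-fold) and ESRRB (4.04 against 0, at least 21.6-fold) were higher. In ovary, IAPP (0 against 47.4, at least 205-fold), DSG4 (0 against 32.4, at least 140-fold) and MMP7 (0 against 29.1, at least 126-fold) were lower and CA3 (4.84 against 0, at least 21.5-fold), AQP10 (3.41 against 0, at least 15.2-fold) and HOXC8 (8.70 against 0.0577, 6.13, SE 0.89) higher. In the pineal gland, where all 3 lactating libraries and no dry library lay closest to another tissue, ZNF593 (0 against 101 ± 22.5, at least 491-fold), the photoreceptor gene RP1 (0 against 47.1, at least 228-fold) and ISL2 (0.0696 against 126 ± 20.8, −10.11, SE 0.49) were lower and HIPK4 (252 ± 65.3 against 2.86 ± 2.69, 6.78, SE 0.59), COL20A1 (5.82 against 0.0791, 6.03, SE 0.97) and CECR5 (3.58 against 0.0791, 5.3, SE 1.04) higher. TPH1 averaged 0.140 CPM in the pineal libraries of lactating goats against 93.9 in those of dry goats. Kidney medulla had 2787 calls, and between 1941 and 2737 with a goat left out. Ovary had 2112, and 479, 478, 490, 915, 764 and 6144 without goats 2, 3, 6, 54, 64 and 73. The pineal gland had 1440, and 693, 3052, 482, 541 and 464 without goats 2, 3, 54, 64 and 73.

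In diaphragm, PDK4, which spares glucose by blocking pyruvate oxidation, stood at 239 ± 12 against 9.96 ± 2.46 CPM (4.34, SE 0.29, adjusted p = 4.09e-06), and ACACB, which makes the malonyl-CoA that restrains fat oxidation, at 65.9 ± 20.6 against 4.25 ± 1.03 (3.74, SE 0.37, adjusted p = 0.000286). The transcription factor gene FOXN4 was higher in diaphragm (93.5 against 1.15, 6.18, SE 0.80) and in masseter (46.4 against 1.17, 4.76, SE 0.42). In diaphragm MEP1A (0.297 against 4.70, −4.24, SE 0.88), ROS1 (5.93 against 64, −3.71, SE 0.30) and the clock-linked BHLHE40 (0.507 against 4.93, −3.52, SE 0.81) were lower, and in masseter cardiac actin ACTC1 (33.1 ± 31.3 against 340 ± 32.3, −3.99, SE 0.58) and SKP1 (0.392 against 7.91, −4.99, SE 0.62). In colon the mucosal genes TFF2 (562 ± 152 against 1.13 ± 1.95, 8.77, SE 0.69, adjusted p = 7.12e-05) and OLFM4 (23.2 ± 32.8 against 0, at least 113-fold) were higher, and the hindgut factor HOXD13 lower (0.0790 against 6.84, −6.28, SE 0.99). Diaphragm had 356 calls, and 154, 210, 128, 124 and 171 without goats 2, 6, 54, 64 and 73. Masseter had 241, and 142, 96, 97, 56, 100 and 139 without goats 2, 3, 6, 54, 64 and 73. Colon had 481, and 185, 167 and 234 without goats 2, 3 and 64, and fewer than 200 without goat 73.

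Across the body, some glucocorticoid-induced genes were higher in the lactating goats. FKBP5 was higher by a log2 mean of 1.46 over 32 tissues (SE 0.11, limma adjusted p = 0.000276) and stood higher in 31 of 31 tissues where it was measured, and ZBTB16, a glucocorticoid-induced transcription factor, was higher by 1.5 (SE 0.16, adjusted p = 0.00131) in 31 of 31. In single tissues they reached 27.0 against 3.13 CPM (FKBP5) and 19.9 against 1.82 (ZBTB16) in thyroid, and FKBP5 9.63 against 1.58 in the bridge. Chosen after their values were seen, PDK4 (1.14, higher in 29 of 33), CPT1A (1.18, 23 of 27) and the fat-sensing receptor PPARA (0.88, 28 of 33) were higher, and the calmodulin gene CALM2 (−0.69), the transferrin receptor TFRC, which overlaps ZDHHC19 (−0.61), the branched-chain amino acid phosphatase PPM1K (−0.86), the mitochondrial fusion gene OPA1 (−0.65) and HMGCS1 of cholesterol synthesis (−0.52) lower. In all, 3247 of 31305 features passed, 1433 higher and 1814 lower, and 204 passed with the median over tissues in place of the mean. The count was 2099, 2071, 1659, 883 and 1203 without goats 2, 3, 54, 64 and 73. In a contrast chosen after results were seen, the same test called 3 features over the 8 brain regions and 5383 over the 24 other tissues. Of 6 lists, the glucocorticoid response was called as higher (3 of 10 called, with PER1 beside FKBP5 and ZBTB16, and 4 adjusted over the list alone, adjusted p = 0.000537, and adjusted p = 0.0521 with an estimated correlation) and the mitochondrially encoded genes as lower (7 of 13 called, among them ND2 at −0.80 and COX1 at −0.37, 10 over the list alone, adjusted p = 3.34e-05, and adjusted p = 0.0516 with an estimated correlation). The other 4 had adjusted p from 0.275 to 0.828. Among these, fry called the interferon list as lower (adjusted p = 0.00355).

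Most features called in many tissues were noncoding. LINC26213 was called lower in 22 tissues and LINC64450 in 12, LINC64525 and KEF96_r01-AS1 in 11 each. LOC106503576-OT1 was called higher in 16 tissues, LOC106504020-OT1 in 15, NFIC-AS1 in 13 with 1 lower, CAPZB-AS1 in 12 and LINC58073 in 11 with 2 lower. The coding gene among these, FLRT1, a neuronal adhesion protein gene that lies within the span of MACROD1 and itself spans other genes, was called higher in 11 tissues and lower in 5, among them the bridge (4.73 ± 1.51 against 19.3 ± 4.15 CPM, −2.0, SE 0.32).

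**Figure D4:**
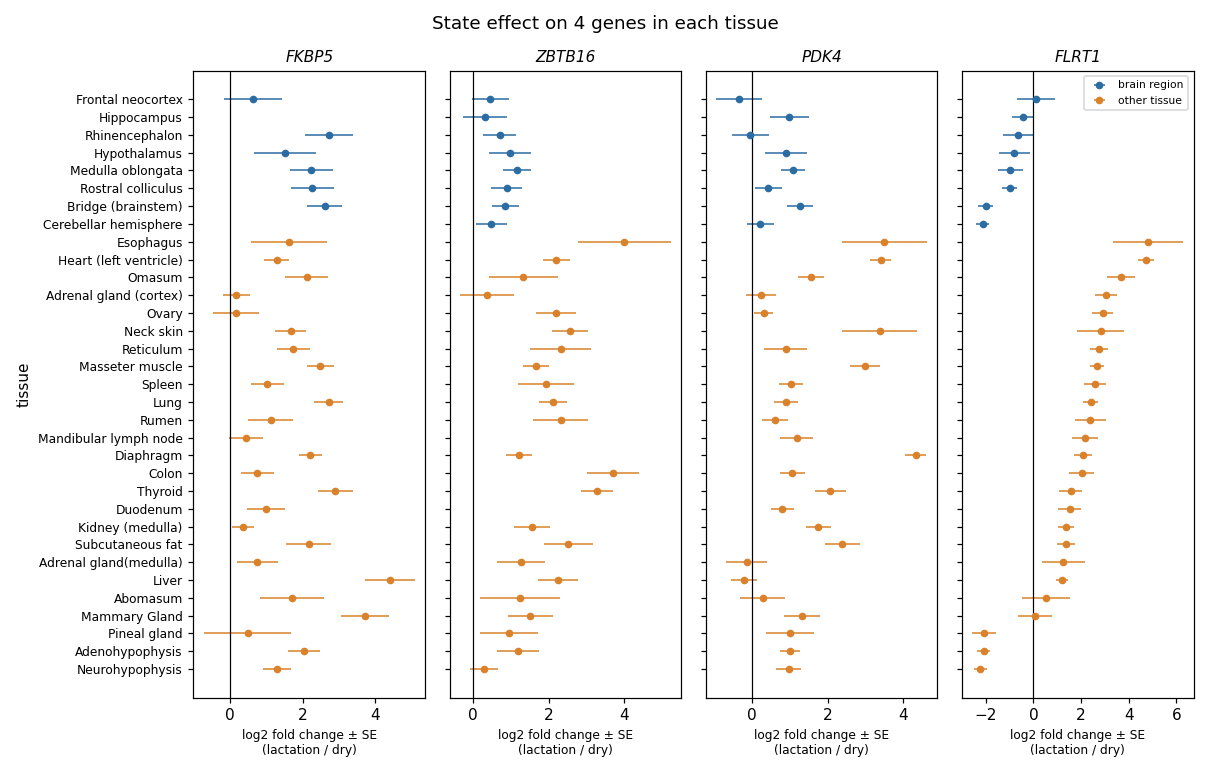
Log2 fold change between lactating and dry goats with its SE in each tissue for FKBP5, ZBTB16, PDK4 and FLRT1, with brain regions set apart. FKBP5 was above 0 in 31 of 31 tissues, and FLRT1 was below 0 in most brain regions and above 0 in most other tissues.

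The mammary effect was then set against that of the other tissues. The difference was largest for the milk protein genes CSN2 (13.95, adjusted p = 0.0022), CSN1S2 (13.46), CSN3 (12.78), GLYCAM1 (11.02) and LALBA (10.31), and it was also called for C9 (5.57), TSPAN6 (4.60), the glutamate transporter SLC1A2 (4.20), PTHLH (4.17) and the developmental factor EYA1 (3.80). In all, 41 features differed, 37 of them with a higher ratio of lactating to dry in the mammary gland than elsewhere and 4 with a lower ratio. Those 4, which stood lower in lactating glands, were LOC108637953-OT1 (−4.40), LOC108635849-OT1 (−3.66), TRNAE-CUC_27-DT1 (−3.33) and OTOF (−3.10). With a goat left out the count fell to 4, 4, 2, 1, 0 and 1 without goats 2, 3, 6, 54, 64 and 73, where an arm of 2 goats remains.

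In the adrenal gland, medulla was set against cortex to ask how the zones differ. The chromaffin genes DBH, which makes noradrenaline (1.93 ± 1.13 CPM in cortex against 11.7 ± 9.35 in medulla, adjusted p = 0.308), and PENK, an opioid precursor (4.40 against 21.4, adjusted p = 0.385), stood higher in medulla with overlap, and FDXR, which serves steroid synthesis, higher in cortex (73 against 39.8, adjusted p = 0.516). CHGA in medulla ran from 37.9 CPM in goat 3 to 1041 in goat 54. By edgeR 0 genes passed, with 1546 at an unadjusted p under 0.05, 66 by DESeq2 and 77 with the goat as a block, 6 higher in cortex and 71 higher in medulla. Adjusted over the list alone, 7 of 11 chromaffin genes were higher in medulla and 0 of 8 steroidogenesis genes differed. With its goat left out of every tissue mean, the medulla library of goat 64 lay closest to cortex (0.929 against 0.914 for medulla). Without libraries closest to another tissue the main fit still called 0 genes.

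No gene was called between the lobes of the pituitary. The intermediate filament gene VIM stood at 3.14 ± 1.83 CPM in adenohypophysis against 7.07 ± 3.17 in neurohypophysis and TRHR, the receptor for thyrotropin-releasing hormone, at 9.84 ± 4.49 against 6.75 ± 3.2, and neither passed. GH1 averaged 881 CPM in adenohypophysis and 878 in neurohypophysis. By edgeR 0 genes passed, with 330 at an unadjusted p under 0.05 and 0 by DESeq2, and 0 of 15 hormone and regulator genes differed when adjusted over the list alone, against 1 of 2 neurohypophysis genes, VIM.

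Rumen and abomasum are a stratified and a glandular chamber of the stomach. Rumen held KRT14 (293 ± 145 CPM against 0, at least 2396-fold higher), KRT6A (534 ± 306 against 0.0810, 12.26, SE 0.93), the cornified envelope enzyme TGM3 (196 ± 167 against 0.0385, 11.43, SE 0.89), KRT36 (295 ± 186 against 0.124, 10.94, SE 0.99) and PMVK of the mevalonate pathway (74.1 against 0, at least 605-fold). Abomasum held MUC5AC (0.992 against 246 ± 251, −8.12, SE 1.19), the acid pump ATP4A (7.84 against 134 ± 90.6, −4.32, SE 1.0) and CLDN18 (44.3 against 113, −1.46, SE 0.28), these 3 with overlap, and lactoferrin LTF (0 against 23.0, at least 229-fold), the antibody transporter PIGR (0.402 against 282, −9.56, SE 1.10), KLHDC7A (0 against 8.88, at least 88.5-fold) and GATA6 (0.175 against 27.7, −7.20, SE 0.69). MUC6 was called too (3.70 against 51.6 ± 90.6, −3.72, SE 1.01), but 235 CPM in the abomasum library of goat 2, which lay closest to duodenum, carried it. Without that library it averaged 15 ± 14.8 and did not pass (adjusted p = 0.0600). In all, 1739 genes passed, 916 higher in rumen and 823 in abomasum. The count was 1119 without goat 3, 1150 without goat 6 and 1067 without goat 73. Of 12 forestomach genes 9 were higher in rumen (11 adjusted over the list alone), and of 5 gastric gland genes 4 in abomasum, MUC6 among them (5 over the list alone). With the abomasum library of goat 2 left out, more gastric genes passed the count filter, and 15 of 16 were higher in abomasum.

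Heart was then set against masseter muscle. The left ventricle held TNNT2 (530 ± 56.3 against 0.209 CPM, 11.32, SE 0.40), RYR2 (606 ± 140 against 0.482, 10.33, SE 0.34), TMEM179 (51.7 against 0.0248, 10.31, SE 0.44) and the atrial hormone gene NPPA (6.0 against 0, at least 83.7-fold). Masseter held TNNT1 of slow fibres (0.826 against 1142 ± 166, −10.50, SE 0.38), MYBPC1 (1.05 against 1116 ± 149, −9.90, SE 0.68), MYOT (0.178 against 93.9, −9.0, SE 0.48), CTXN3 (0 against 9.33, at least 144-fold), the calcium release channel RYR1 (0.6 against 191, −7.89, SE 0.91) and the myogenic factor MYF6 (0.0558 against 11.6, −7.06, SE 0.63). In all, 2398 genes passed, 1214 higher in heart and 1184 in masseter. Of 14 cardiac genes 10 were higher in heart in both adjustments, and TNNC1, which slow skeletal fibres share and which was picked out after its value was seen, was higher in masseter (127 against 276, with 2 members adjusted over the list alone). All 7 skeletal fibre genes were higher in masseter, also adjusted over the list alone.

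The last pair was cerebellum and frontal neocortex. The cerebellum held EN2 (5.37 ± 0.873 CPM against 0, at least 54.5-fold), the granule cell receptor GABRA6 (22.5 against 0.146, 6.76, SE 0.63), STARD5 (30.0 against 0.206, 6.65, SE 0.39), LHX1 (6.93 against 0.0361, 6.51, SE 0.65), CBLN1 (33.2 against 0.307, 6.28, SE 0.49) and ZIC4 (11.8 against 0.0840, 6.15, SE 0.60). The neocortex held IL9 (0 against 6.02, at least 52.2-fold), ENC1 (0.192 against 25.3, −7.33, SE 0.76), the synaptic gene NRGN (0.261 against 25.4, −6.86, SE 0.74), TRPV6 (0.877 against 76.0, −6.81, SE 0.43) and, with overlap, the kinase CAMK2A (4.03 against 68.5, −4.58, SE 0.67) and the layer markers LMO4 (2.59 against 17.4, −3.24, SE 0.61) and CUX2 (2.05 against 6.49, −2.07, SE 0.55). In all, 3762 genes passed, 1806 higher in cerebellum and 1956 in neocortex, which became 4233 and 1080 with total counts alone as scaling. Of 16 cerebellar genes 14 were higher in cerebellum (15 adjusted over the list alone), and of 6 neocortex genes 5 in neocortex, while RASGRF2, picked out after its value was seen, was higher in cerebellum (39.8 against 18.5).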

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

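All tests of explanations in this part were chosen after the result was seen, except the thinning of libraries. The body-wide count without kidney medulla, ovary and pineal gland was predicted before it was made, but those tissues were picked after their calls were seen.

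In 6 of 33 tissues, a single library correlated less with its tissue than the other 5 by a margin that chance gives in about 1 in 20 groups. No total count stood apart in this way. The 6 libraries were the abomasum of goat 2 (0.743, others 0.888 to 0.920), the hypothalamus of goat 2 (0.885, others 0.933 to 0.947), the rumen of goat 54 (0.873, others 0.917 to 0.932), and for goat 64 the adenohypophysis (0.899, others 0.928 to 0.943), liver (0.896, others 0.917 to 0.923) and rostral colliculus (0.914, others 0.942 to 0.945). The difference between groups in the mammary effect (41 features, described in the report) was called by a test of the difference itself.

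The strand of the counts bears on most values, and the ND4 antisense feature exceeded ND4 in every library (100%), although ND4 is an abundant mitochondrial transcript, while for ND5 this held in 132 libraries, and 91.4% of 2137 antisense features exceeded the gene they are named for (median ratio 19.9). Across the 33 tissues these features followed their host genes (median r 0.566, against 0.157 for shuffled hosts), while among housekeeping genes ACTB and GAPDH peaked at 69.1 and 172 CPM but EEF1A1 at 1798. For the mitochondrial 16S rRNA the antisense feature was the higher in 195 libraries (mean 896 against 55.6 CPM). A candidate explanation is that reads of the strand-specific kit were largely assigned to the strand opposite to their gene. Antisense features may then carry the signal of their hosts. ND5, which overlaps ND6, and EEF1A1 leave it open whether this would hold for every gene alike. A few dominant features do not account for the lncRNA share, which stayed at a median of 78.0% without the 10 most abundant, and no biological explanation was tested.

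The calls in kidney medulla, ovary and pineal gland may reflect what was sampled. In kidney, 9 of 10 tested proximal tubule and glomerulus genes were lower in lactating goats, with LRP2 at 83.6 against 983 CPM, while 3 of 8 renal medulla genes were higher, with SLC12A1 above 200 CPM in every lactating goat and below 50 in every dry goat. In ovary, 4 of 4 tested cilia genes were lower, and DNAH5 stood at 147 and 150 CPM in goats 54 and 64 but at 2.71 in goat 73, so the dry goats themselves differed. In the pineal gland, 4 of 5 tested pineal genes were lower in lactating goats, among them TPH1. All 3 lactating libraries and no dry library lay closest to another brain tissue, and the choroid plexus gene TTR reached 1369 CPM in goat 3 alone. A largest ratio of library totals between the states of 1.17 argues against library size, and an effect of lactation on these organs, or of other differences between the goats, stays open as untested.

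The body-wide difference is not a plain shift shared by all tissues. The state effect differed between the 8 brain regions and the 24 other tissues for 304 features (limma, 5504 at an unadjusted p under 0.05), and 280 of these had opposite signs, which argues against a shared shift for those features. Of the 3247 body-wide features, 76.6% had the same direction in brain as elsewhere. They were called on a mean that includes the 8 brain regions, which itself raises this share. The share therefore leaves a shared shift open for the rest. Run over the 8 brain regions alone, the test called just 3 features, against 5383 over the 24 other tissues. The body-wide calls therefore do not show a difference in brain. Thinning the libraries of each tissue to 1 total left 3197 called, 3023 of them shared with the same direction, and without kidney medulla, ovary and pineal gland 2471 were called, so neither library size nor those organs account for the pattern. Lactation, with its hormones and energy demand, and any unrecorded difference in handling, feeding or sampling between the 2 sets of goats may each explain it, and the design confounds them.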

How the results depend on the processing

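The settings without lncRNA features, without libraries closest to another tissue, without kidney medulla, ovary and pineal gland, without antisense features, without goat 2 for the gastric genes, and with goats left out of the lncRNA tau, of the tissue means for library identity and of the lists in every tissue but the mammary gland were chosen after the data were seen. With 3 goats per state, a call rests on few animals, and leaving a goat out moved most counts. Tau from length-scaled values was not run, since the length table holds offsets. Without libraries closest to another tissue, there is no value for the adenohypophysis, the pituitary pair or heart against masseter. For all changes below the cause was not tested. With fewer goats or fewer features some counts fell and others rose.

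With goats left out in turn, counts ran from 37 to 193 in mammary gland, 45 to 254 in liver, 0 to 4 in subcutaneous fat, 112 to 322 in adenohypophysis, 0 to 4 in hypothalamus, 0 to 28 in duodenum, 6047 to 11020 over the other tissues, 883 to 2461 body-wide, 0 to 4 for the mammary difference and 1067 to 2080 for rumen against abomasum. Heart against masseter (1874 to 2290), cerebellum against neocortex (2778 to 4635), called mammary lists (7 to 10), tau (4558 to 4714), tissue-enriched features (515 to 566) and the lncRNA difference in tau (−0.141 to −0.138) moved less. Without a count filter the calls were 630 in mammary gland, 980 in liver, 412 in fat, 1176 in adenohypophysis, 45 in hypothalamus, 390 in duodenum and 25115 over the other tissues. DESeq2 gave 729, 578, 170, 798, 32, 166 and 19159 for the same comparisons, 66 for the adrenal pair and 3306 for rumen against abomasum. A single fit over all libraries gave 974 in mammary gland, 204 in fat, 3 in adenohypophysis, 6 in hypothalamus and 70 in duodenum. With the goat as a replicate block the adrenal pair had 77 calls, and the block moved no other pair's count by more than 1.5 times. Without lncRNA features the counts were 80 in mammary gland, 102 in liver, 6 in fat, 6402 over the other tissues, 16 for the mammary difference, 784 for rumen, 1322 for heart, 1799 for cerebellum, 2898 for tau and 307 tissue-enriched. Without libraries closest to another tissue they were 4 in hypothalamus, 28 in duodenum, 5757 for cerebellum, 874 tissue-enriched and −0.134 for the lncRNA difference, and without kidney medulla, ovary and pineal gland 4460 over the other tissues. A prior count of 0.5 gave 84 and of 5 gave 19 for the mammary difference, and the median over tissues gave 204 body-wide. Tau of at least 0.8 was reached by 9889 features on untransformed CPM, 1991 with a pseudocount of 0.1, 10484 without a filter and 2143 at a minimum of 5 CPM. The lncRNA difference was −0.0525 untransformed, −0.109 without a filter, −0.142 at 5 CPM and −0.116 without antisense features. Tissue-enriched features numbered 314 at a fold of 10 and 1237 by means alone. With an estimated correlation 0 mammary lists were called.

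Of 54 genes named in the mammary gland, 25 were called in the main fit. Over 702 values, 605 kept direction and call, which includes genes that stayed uncalled. The 78 values that lost the call (69 with a goat left out) all belong to those 25 genes, of which 8 kept it throughout. Another 18 values gained the call (17 by DESeq2 or without a filter) and 1 reversed, that of JCHAIN. This gene was not called, and its log2 fold change ran from −0.0537 without goat 54 to 1.89 without goat 64. RLE and the offsets as scaling, and a minimum log2 fold change of 1, moved none of these counts of genes by more than 1.5 times.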

Other observations

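The brain contrast, the split tests and the gene lists on metabolism in this part were chosen after results were seen, except the splits of the planned comparisons.

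Genes in tissues not yet described also differed between lactating and dry goats. In the thyroid, the vesicle traffic gene RAB2B was lower (4.65 ± 2.36 against 22.5 ± 4.56 CPM, −2.39, SE 0.40) and the energy-sensing kinase subunit PRKAA2 too (235 ± 8.65 against 490 ± 71.0, −1.19, SE 0.16). In the left ventricle the complement gene C7 was lower (3.72 against 21.2, −2.86, SE 0.42), and in the lung the alveolar gene RTKN2 was lower (1.20 against 9.27, −3.10, SE 0.64). In the mandibular lymph node PPARA (69.7 against 14.2, 1.83, SE 0.27) and the ribosome assembly gene BYSL (39.9 against 6.89, 2.08, SE 0.28) were higher and XBP1, the plasma cell factor, lower (21.4 against 47.8, −1.60, SE 0.26). In the reticulum the carbonic anhydrase CA9 was higher (57.7 against 5.52, 3.22, SE 0.49), in the omasum HOXB3 lower (8.11 against 27.9, −1.97, SE 0.27), and in the spleen the neutrophil gene S100A9 higher (20.8 ± 22.0 against 0.721 ± 0.903, 4.73, SE 0.97). In the adrenal cortex LIPE was higher (9.45 against 0.365, 4.45, SE 0.77).

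The brain regions took a different course for some genes. FLRT1, which lies within MACROD1, had a mean log2 effect of −0.90 in the 8 brain regions and 1.81 in the 24 other tissues (limma adjusted p of the difference 0.00772). CPT1A was at −0.06 in brain and 1.60 elsewhere (adjusted p = 0.0330), the chloride channel gene CLCN2, which overlaps FAM131A, at −0.46 and 1.06 (adjusted p = 0.0245), and SERPIND1, a thrombin inhibitor, at −0.59 and 1.13 (adjusted p = 0.0245). CPT1A passed the count filter in 4 of the 8 brain regions, where 1 stood higher, and in 22 of the 24 other tissues, where 21 did. Low counts with a prior count of 2 can draw its brain value towards 0, which was not tested. FKBP5 (1.78 in brain and 1.35 elsewhere, adjusted p = 0.363) and ZBTB16 (0.66 and 1.78, difference −1.12, SE 0.27, adjusted p = 0.0964) did not pass, which leaves a difference open. Tissue effects correlated with the mean effect of the other tissues from −0.145 in the adenohypophysis to 0.689 in the lung, across 7822 genes, which are not independent replicates. Body-wide lists for fatty acid oxidation (adjusted p = 0.277), cholesterol synthesis (0.140), lipogenesis (0.172), gluconeogenesis (0.809) and proliferation (0.513) were not called by camera. Fry called fatty acid oxidation as higher and cholesterol synthesis and proliferation as lower (adjusted p = 0.0429 for each), although 8 of 17 fatty acid oxidation genes stood higher and 9 lower.

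The duodenum library of goat 2 held stomach transcripts, with the acid pump genes ATP4A at 118 and ATP4B at 222 CPM, GKN2 at 427, MUC5AC at 882 and the pepsinogen gene PGC at 258. The abomasum library of goat 2 lacked most gastric transcripts, with PGC, ATP4B, TFF1, GKN1 and GKN2 at 0, ATP4A at 0.909 and MUC5AC at 1.36 CPM, where the other abomasum libraries averaged 82.1 for PGC and 408 for ATP4B. It held MUC6 at 235. No swap was tested.

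Splits of the same 6 goats into other sets of 3 number 10 with the real one, too few to give a share under 0.05. The real split gave 159 higher and 33 lower genes in mammary gland (highest other 0), 243 in liver (0), 516 in adenohypophysis (2), 10799 over the other tissues (199), 3247 body-wide (5), 41 for the mammary difference (0) and 304 for the brain difference (2), and in each of these 1 of 10 splits, the real one, gave as many. In subcutaneous fat, hypothalamus and duodenum the real split gave 0 calls (highest other 1), so these splits test nothing there. For mammary lists, 4 of 10 splits called at least the real 8, and the highest other called 11. For the tissue pairs, 100 of 462 splits were drawn. The counts argue against chance for rumen against abomasum (1739, highest other 529), heart against masseter (2398, highest other 1) and cerebellum against neocortex (3762, highest other 1). In each, 1 of 100 splits, the real one, gave as many, which is the smallest share these splits can give. For the adrenal pair (real 0) and the pituitary pair (real 0, highest other 22) a real count of 0 leaves nothing to test. The split that called 617 genes in the adrenal pair parted the dry from the lactating goats, which points to a structure of the samples by goat set. The split with 529 put rumen of goat 54 with 5 abomasum libraries, without that of goat 2. Few of the drawn splits parted the tissues of every goat as the real one does, so all 32 that do were run too. The highest other was 275 for rumen against abomasum, 0 for heart against masseter and 92 for cerebellum against neocortex. In each, 1 of 32, the real one, gave as many, a share under 0.05 and the smallest that 32 splits can give. This argues against chance there too but cannot exclude it. With the goat as a block the adrenal pair had 77 calls (highest other 1), again 1 of 32.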
